A study of Mus musculus with 5 samples.

How the data were processed

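The data are UMI counts of single cells from wild-type C57BL/6 mouse embryos at E9.5 (2 batches) and E10 (3 batches). Per the labels' protocols, blood was taken from the heart, circulating cells negative for TER119, CD41, CD43 and CD45 were sorted, single cells were picked by hand, and libraries were made with a modified STRT-seq protocol, in which a cell barcode of 8 bases and a UMI of 8 bases mark each molecule. The series description calls the method Smart-Seq. Per the submitters' processing notes, base calls came from CASAVA 1.8, reads were aligned to the mm10 genome with TopHat2 2.0.12, and UMIs per gene were counted with HTSeq, for which no version is given. The deposited table holds these counts, whole numbers for 24411 genes and 95 spike-in rows against 480 columns, 96 for each batch. Column names carry a batch number, and the match to the 5 samples rests on that number alone. The list of barcodes was not used here. No strand setting is recorded, so overlapping genes, as in the Hox clusters and at imprinted loci, cannot be told apart, and genes with near-identical copies are uncertain.

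A cell was kept with at least 1000 genes and 5000 UMIs. The table has no rows for mitochondrially encoded genes, so the planned mitochondrial limit could not be applied and 30 of the 31 gene lists could be tested. Of the 480 columns 327 passed, and 111 held 0 UMIs. A passing well at under 10% of the UMIs of a passing well of the same number in another batch was compared with that batch. The 23 wells whose best match was the same well number were left out, which left 304 cells. This step was added after the data were seen, and wells below the limits were not compared. The 369 columns with UMIs all held distinct counts, and the sums of the 5 batches correlated at r of 0.938 to 0.968 on the log2 scale, across genes, with no pair identical. No doublet caller was run, because the cells were picked by hand into single wells.

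Cells were scaled to counts per 10000, with 1 added before the log, and clustered with scanpy 1.11.5 and leidenalg 0.10.2 under Python 3.11.15, from 2000 variable genes, 20 principal components, 15 neighbours, a Leiden resolution of 1.0 and seed 0, without batch integration. The 503 genes of the fixed lists that were in the table and were not cell type markers were left out of clustering, with globin, ribosomal and sex-linked genes. A cluster was named from 18 fixed marker lists when at least 3 markers of a list had a median of 20 CPM and 2-fold the level of the other cells, unless its 10 leading genes held more markers of another list than of its own. Leading genes were ranked by the ratio of CPM with 10 added, among genes with a UMI in 25% of the cluster's cells. The markers were fixed before the data were examined, as were the gene lists, the tests and the rule for naming genes. The use of the median followed a first trial with the mean, which is kept as an alternative, and both the Dppa5a-led group and the pooled remaining clusters were defined after the data were seen. Names are therefore rebuilt and can differ from those of the study.

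Shares of cells per batch carry 95% exact (Clopper-Pearson) binomial intervals, and a share of 0 an upper limit of 3 counts. Stages were compared by two-sided exact permutation of the 5 batches over 10 splits, which cannot give a p below 0.1. Scores for cell cycle phase were computed on cells thinned to 10000 UMIs.

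Gene tests used counts summed per batch, or per batch and class, in edgeR 4.0.16 under R 4.3.3, with filterByExpr, TMM scaling and the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The CPM of these sums used the TMM-scaled totals of each fit, so the level of the same sum differs between fits. In the remaining clusters of E9.5 replicate 2, Cyr61 stood at 2283 CPM in the stage fit. The same sum gave 2225 and 1668 CPM in the neural or neural crest-like and erythroid-like interactions. Each batch holds 1 stage, so batch was not a term in the stage fits, and batch and stage cannot be told apart beyond the replicates. Class comparisons and the interaction of class and stage carried batch as a block, since both sums of a batch come from the same collection. A sum needed 10 cells, and 3 for the neural or neural crest-like class, a minimum chosen after the cell numbers were seen. Class comparisons were read only for list genes left out of clustering. These genes can still vary with the clustering genes in the same cells, so the p-values do not test a grouping made independently. The standard error of a log2 fold change was its size divided by the square root of the F statistic. DESeq2 1.42.0 was the second tool. Lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, all in limma 3.58.1 on voom weights, with adjustment over lists.

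Genes are named by a fixed rule. It takes the 10 largest log2 fold changes per direction among genes past the threshold, with a mean count of at least 10 and the same sign in every batch or full separation of the groups, and up to 4 passing members of each list, or the 2 with the highest CPM where none passed. The text gives a selection of these. In stage comparisons without a passing gene, members of the lists that passed camera are named, a choice made after the results were seen, and Prrx1 and other cluster markers are given as descriptions. The interactions were read on all genes, those used for clustering included.

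Each fit was tested on simulated data with 200 changed genes among the 10174 to 14104 tested. In the stage fit of all cells 1.49% of 2-fold, 28.4% of 4-fold and 66.7% of 8-fold changes were recovered, and in the remaining clusters 2.99%, 32.8% and 66.7%. For the neural or neural crest-like stage fit the values were 0%, 10.4% and 34.8%. In the class fits they were 4.48%, 59.7% and 75.8% for erythroid-like cells and 14.9%, 52.2% and 80.3% for neural or neural crest-like cells. The interactions recovered 0%, 5.97% and 10.6% for erythroid-like cells and 0%, 8.96% and 31.8% for neural or neural crest-like cells. False calls numbered 0 to 6 per fit. Simulated counts took the dispersion from its trend over expression, without the spread of single genes about that trend, and each gene was drawn independently. Recovery and false calls in the real fits can therefore differ from these values.

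The alternatives tried were DESeq2 size factors, the DESeq2 test, no low count filter, a stricter cell filter of 2000 genes and 10000 UMIs, cells without over 5% globin UMIs, thinned cells, other minimum cell numbers, other clustering settings, leaving out each batch in turn and, for class comparisons, no replicate block. Added after the data were seen were keeping the copied wells, leaving out the blood classes, and naming clusters by mean levels. So were the minimum of 3 cells, thinned cells in the fit of the remaining clusters, and the alternatives of the neural or neural crest-like fits and of the interactions. Left out were 176 columns, of which 65 held at least 1 UMI, the 23 copied wells among them, and 336232 UMIs in all.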

Results

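The data were molecule counts of single cells taken from the blood of mouse embryos at 2 stages of mid-gestation, embryonic day 9.5 (E9.5) and embryonic day 10 (E10). Per the labels, blood was collected from the heart and cells were sorted as negative for TER119, CD41, CD43 and CD45, surface proteins of erythroid cells, platelets and their precursors, and other blood cells. The series title names the aim, a description of circulating cells that are not of the blood lineage. E9.5 was represented by 2 replicate batches and E10 by 3, each with 96 columns of 1 well each, 480 columns in all. The cells are not replicates, so every test of a stage or a class of cells used sums or shares per batch. Nothing in the labels says whether the batches came from separate litters, so each p-value of a gene or a share measures the spread between these samples. The p-values of camera with its preset correlation set list genes against other genes and do not measure that spread.

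After filtering, 304 cells were kept, against 300 cells stated in the series description. They comprised 26 cells of E9.5 replicate 1, 46 of E9.5 replicate 2, 96 of E10 replicate 1, 72 of E10 replicate 2 and 64 of E10 replicate 3. In the same order the kept cells held 7545865, 8380810, 44574605, 24267995 and 20191553 unique molecular identifiers (UMIs, tags that count molecules). The median was 302982 UMIs and 7341.5 genes per cell, and cells ranged from 7608 to 1407021 UMIs. Haemoglobin genes took a median 0.664%, 1.73%, 0.0350%, 6.32% and 0.984% of a cell's UMIs in the batches in that order, although the sort excluded TER119-positive cells. Ptprc, the gene of CD45, had 0 UMIs in the kept cells.

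The kept cells exclude 23 wells that repeated the profile of the well of the same number in another batch of the same stage at a small share of its UMIs. Of these, 20 were wells between 73 and 96 of E10 replicate 2, which held 1.68% to 4.66% of the UMIs of the matching wells of E10 replicate 3. Their median correlation with the matching well was 0.840, across genes within a cell, against 0.611 with the other wells. A further 2 such wells lay in E9.5 replicate 1 and 1 in E9.5 replicate 2.

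**Figure D1:**
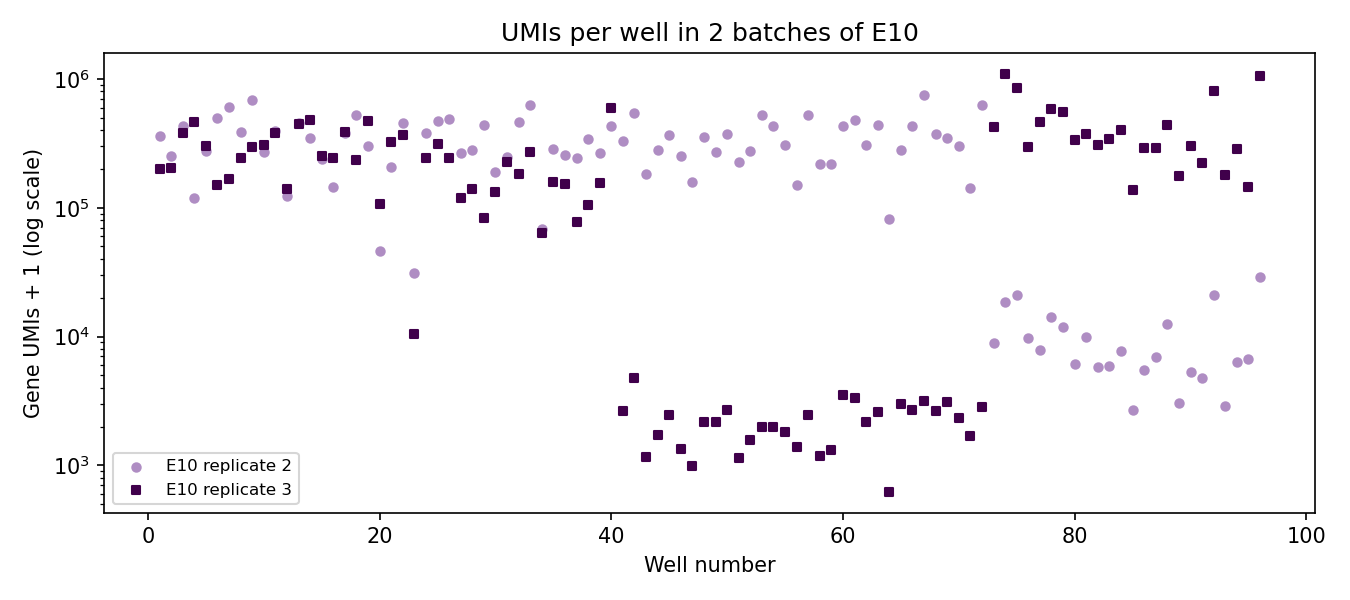
UMIs per well on a log axis against well number in E10 replicate 2 and E10 replicate 3, 96 wells each, 1 point per well. The 20 wells of E10 replicate 2 taken as copies lie between well 73 and well 96 and hold at most 4.66% of the UMIs of the same wells of E10 replicate 3.

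Clustering gave 11 clusters, of which 4 were named by their markers. Clusters 5 and 10 were erythroid-like, with the embryonic globin gene Hbb-y at a median CPM (the count scaled to the cell's total) of 78000 and the haem synthesis gene Alas2 at 1100. Cluster 6 was haematopoietic progenitor-like, with the receptor gene Kit at a median of 78.6 CPM, the transcription factor genes Myb at 99.2 CPM and Gfi1b at 111 CPM, and Spn, the gene of CD43, at 27.5 CPM. Cluster 4 was neural or neural crest-like, with the neurofilament gene Nefm at 1250 CPM, the neuronal tubulin gene Tubb3 at 443 CPM and the neural crest gene Sox10 at 114 CPM. These genes defined the clusters and are given as descriptions only. The CPM of sums per batch, given in the comparisons below, was TMM-scaled within each fit and is not comparable between fits.

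Cluster 8, of 21 cells, was led by genes of early embryonic and pluripotent cells, with Dppa5a at a median of 2940 CPM, Zfp42 at 686 CPM, Nanog at 237 CPM and Tdgf1 at 225 CPM, while Pou5f1 stood at 13.3 CPM and the germ cell gene Dppa3 at 0. It reached 2 of the 3 germ cell markers needed and was left without a cell type name. Cluster 9 had 8 mesenchymal markers, with the collagen genes Col3a1 at a mean of 1040 CPM and Col1a2 at 954 CPM and the limb and head mesenchyme factor Prrx1 at 546 CPM. It stayed unnamed because its leading genes held the endothelial marker Flt1 and no mesenchymal marker. Cluster 1 was also left unnamed, with 5 mesenchymal markers, Pdgfra, Pdgfrb, Col1a1, Col1a2 and Col3a1, while its leading genes were of smooth muscle and endothelium, with Acta2 at a mean of 578 CPM, Cldn5 at 145 CPM and Plvap at 134 CPM. Cluster 2 was led by the forebrain and eye regulators Pax6, at a mean of 297 CPM, Six3 and Lhx9. The mesenchymal markers Prrx1 and Prrx2 also reached the marker levels of the naming rule in it. Cluster 3 had the dermomyotome and neural tube gene Pax3, at 271 CPM, among its leading genes. Cluster 7 was led by Car12, at 182 CPM, and the basement membrane genes Col4a1, at 1290 CPM, Col4a2 and Lama1, followed by Hoxc10, at 191 CPM, and the heart muscle gene Tnnt2, at 71.1 CPM. Cluster 0 was led by the histone gene Hist2h2ac and by Mpped2, and the mesenchymal markers Twist1 and Twist2 reached the levels of the rule in it. Clusters 0, 1, 2, 3, 7 and 9 are grouped here as the remaining clusters, a mixed group of 180 cells.

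**Figure D2:**
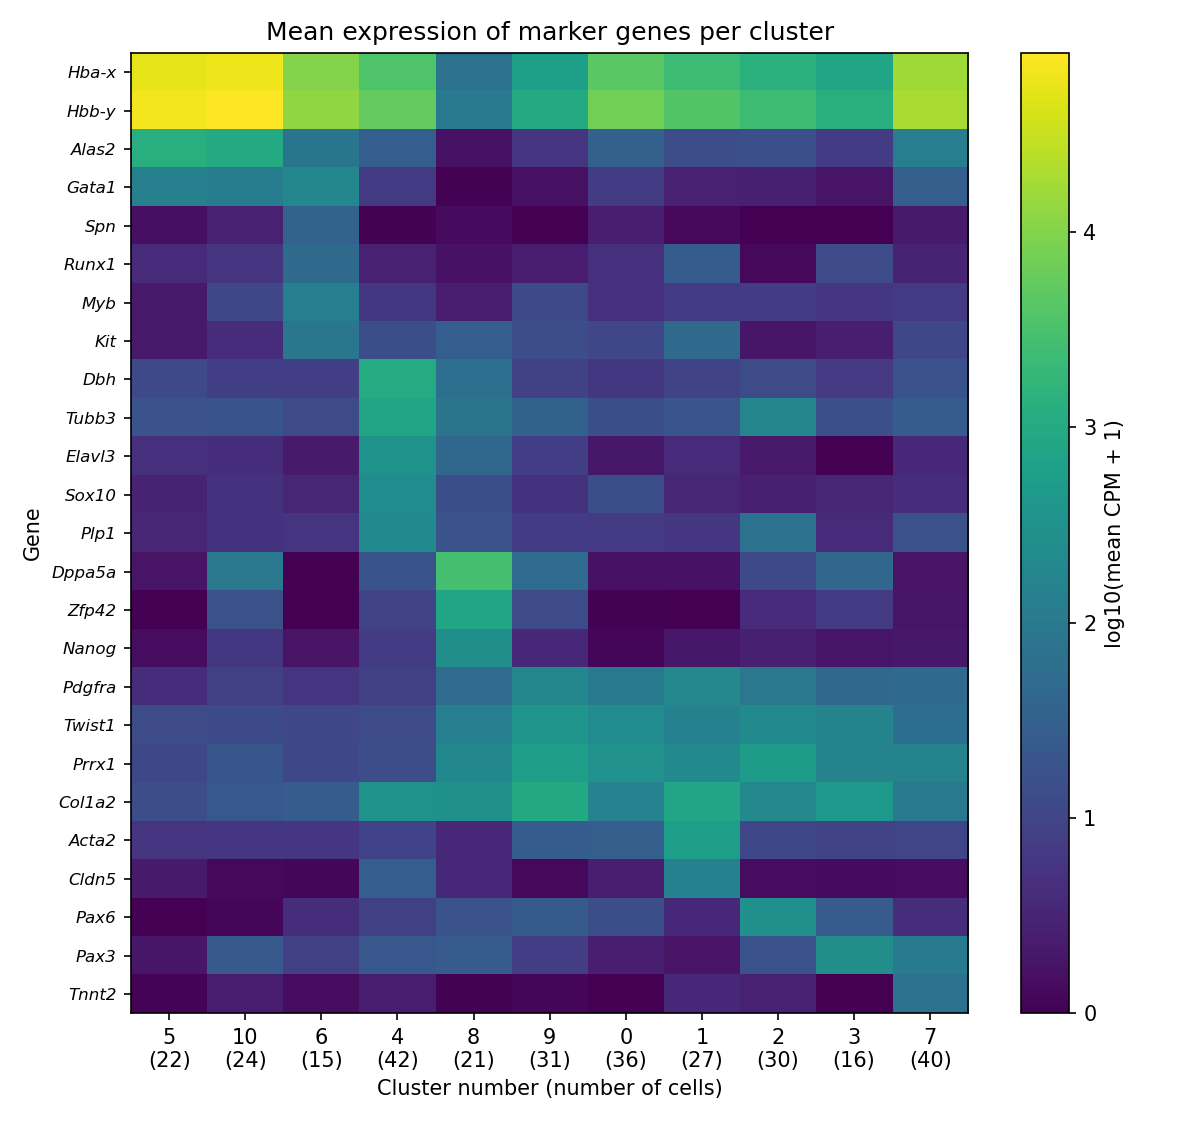
Marker genes against clusters, with the colour giving the mean level as a logarithm of CPM in the kept cells of the 5 batches together. Haemoglobin genes peak in clusters 5 and 10, progenitor genes in cluster 6, neural genes in cluster 4 and Dppa5a, at a median of 2940 CPM, in cluster 8.

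Erythroid-like cells made up 3.85% of the kept cells of E9.5 replicate 1 (95% exact binomial interval 0.0973% to 19.6%), 21.7% of E9.5 replicate 2 (10.9% to 36.4%), 1.04% of E10 replicate 1 (0.0264% to 5.67%), 31.9% of E10 replicate 2 (21.4% to 44.0%) and 17.2% of E10 replicate 3 (8.9% to 28.7%). Haematopoietic progenitor-like cells made up 8.7%, 11.1% and 4.69% in E9.5 replicate 2, E10 replicate 2 and E10 replicate 3. None were found in E9.5 replicate 1 and in E10 replicate 1, which allows shares of up to 11.5% and 3.12% by the limit of 3 counts. The exact intervals reach 13.2% and 3.77%. Neural or neural crest-like cells were seen in every batch, at 11.5% and 15.2% in the E9.5 replicates and 9.38%, 5.56% and 29.7% in the E10 replicates. The Dppa5a-led cells made up 21.9% of E10 replicate 1 (14.1% to 31.5%) and 0 in the other 4 batches, which allows 11.5%, 6.52%, 4.17% and 4.69% by the limit of 3 counts. The exact intervals of these 4 batches reach 13.2%, 7.71%, 4.99% and 5.6%. The sort against TER119, CD41, CD43 and CD45 can set the shares of the blood classes, the wells held hand-picked cells, and the intervals and limits cover counting error only.

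The change of these shares with stage did not exceed the spread between batches in any class. Erythroid-like cells averaged 12.8% ± 12.7 (SD, n = 2) at E9.5 and 16.7% ± 15.5 (SD, n = 3) at E10, with p = 0.9 in a two-sided exact permutation test over the 10 splits of the batches, whose smallest possible p is 0.1. Haematopoietic progenitor-like cells averaged 4.35% ± 6.15 and 5.27% ± 5.58 (exact permutation p = 1.0), and neural or neural crest-like cells 13.4% ± 2.6 and 14.9% ± 13.0 (exact permutation p = 1.0). The Dppa5a-led cells averaged 0% and 7.29% ± 12.6 (exact permutation p = 1.0), and the remaining clusters 69.5% ± 21.4 and 55.8% ± 10.4 (exact permutation p = 0.5).

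**Figure D3:**
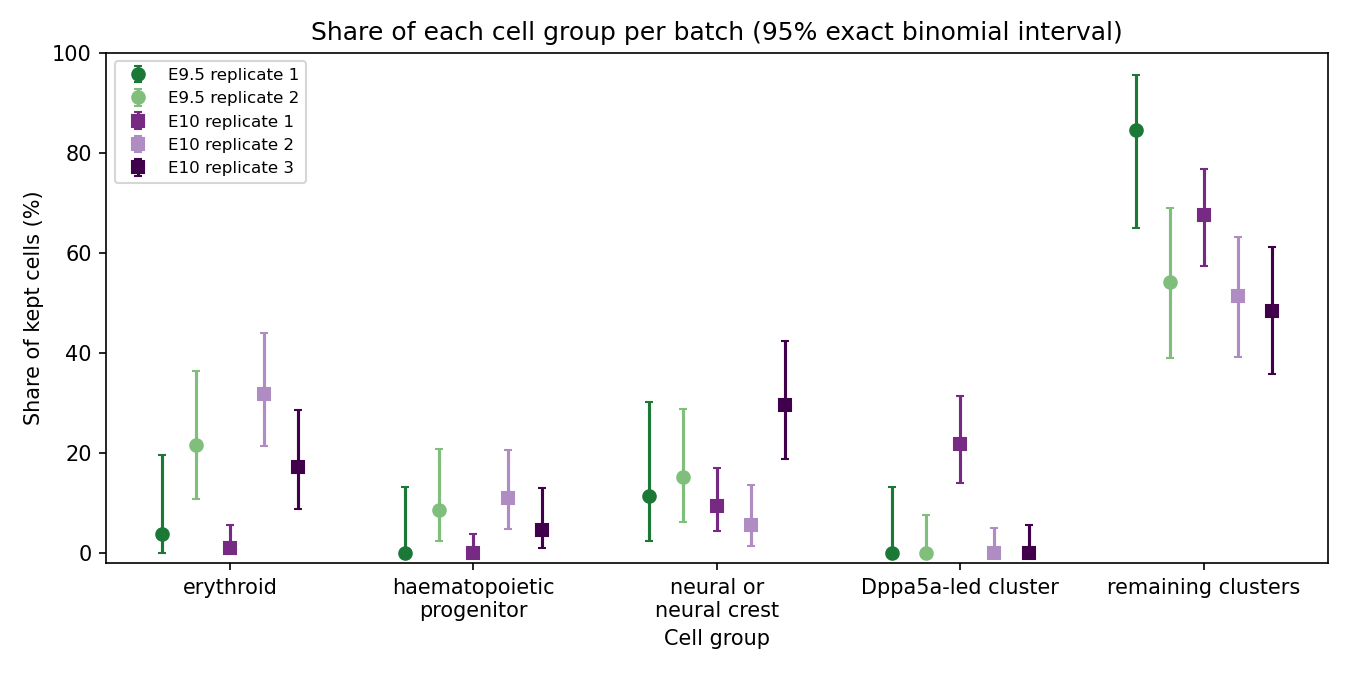
Share of kept cells, in percent, of each class of cells in each of the 5 batches, with bars for the 95% exact binomial intervals. Dppa5a-led cells appear in E10 replicate 1 alone, at 21.9%, and erythroid-like cells span 1.04% to 31.9%.

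Cycling genes were read at the same depth in every cell, with each cell thinned to 10000 UMIs, which left out 2 cells of E10 replicate 1. A score above 0 for the S-phase genes, which serve DNA replication, was found in 68.6% ± 4.49 (SD, n = 2) of the cells at E9.5 and 76.5% ± 13.1 (SD, n = 3) at E10 (two-sided exact permutation p = 0.7). For the G2 and M phase genes, which serve mitosis, the shares were 70.7% ± 7.57 and 74.4% ± 16.2 (exact permutation p = 0.9). The S-phase shares of the E10 replicates were 69.1%, 91.7% and 68.8%, so E10 replicate 2 alone carried the higher mean. Without thinning the S-phase shares were 74.6% and 78.3%, and the G2 and M phase shares 77.8% and 80.4%. Over all alternatives the difference of E10 minus E9.5 ranged from 0.388 to 11.8 percentage points for S-phase genes. For G2 and M phase genes it ranged from -5.73 to 8.97. In neural or neural crest-like cells the S-phase share was 45.2% ± 16.8 at E9.5 and 34.0% ± 35.6 at E10 (exact permutation p = 0.7). The E9.5 replicates stood at 33.3% of 3 cells and 57.1% of 7 cells. The E10 replicates stood at 11.1% of 9 cells, 75.0% of 4 cells and 15.8% of 19 cells, so the E10 mean leans on the 4 cells. In the remaining clusters the S-phase share was 68.1% ± 0.129 and 84.0% ± 9.81 (exact permutation p = 0.2), and 78.6% ± 1.93 and 82.9% ± 11.6 without thinning (exact permutation p = 0.7). The smallest p that the 10 splits allow is 0.1, and the scores alone do not establish cycling.

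Erythroid-like cells held more transcript of the hexokinase gene Hk1, the growth arrest gene Gadd45a and the respiratory chain gene Cox6a1 than the remaining clusters of the same batches. Hk1 stood at 137 ± 56.7 CPM (mean ± SD, n = 3 batches) in erythroid-like cells and 20.02 ± 14.0 CPM in the remaining clusters, a log2 fold change of 2.89 (SE 0.36) with an adjusted p of 9.57e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Gadd45a stood at 61.0 ± 11.8 against 7.98 ± 0.602 CPM (log2 fold change 2.91, SE 0.43) and Cox6a1 at 1974 ± 525 against 601 ± 93.5 CPM (1.69, SE 0.24). Lower in erythroid-like cells were the growth factor gene Ptn, at 8.60 ± 5.38 against 281 ± 188 CPM (log2 fold change -5.03, SE 0.32), the chromatin gene Hmga2 of proliferating embryonic cells, at 83.7 ± 73.8 against 908 ± 121 CPM (-3.83, SE 0.37), and the BMP target Id2, at 73.7 ± 21.5 against 811 ± 152 CPM (-3.48, SE 0.28). For Ptn the adjusted p was 1.13e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each of these genes differed the same way in 3 of 3 batches.

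That comparison asked what separates the erythroid-like cells beyond the genes that defined the clusters, and only the fixed lists of genes left out of clustering were read. The classes were formed from these same cells, and list genes can vary with the clustering genes. The p-values of the class comparisons therefore describe the groups as formed. It used E9.5 replicate 2, E10 replicate 2 and E10 replicate 3, which had at least 10 cells of both groups. The erythroid-like cells were in cluster 5 in E9.5 replicate 2 and E10 replicate 3 and in cluster 10 in E10 replicate 2. Of 431 list genes, 220 passed an adjusted p of 0.05, 79 higher and 141 lower in erythroid-like cells, against 273 at an unadjusted p under 0.05 and 239 by DESeq2, of which 216 were shared. Without E9.5 replicate 2 the count was 96, with 14 higher and 82 lower.

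Among the lists, ribosomal protein genes were higher in erythroid-like cells in 22 of 22 cases, both over all genes and adjusted over the list alone, with an adjusted p of 2.13e-26 by camera with its preset correlation and adjusted p = 0.388 with an estimated correlation. The small subunit gene Rps2 stood at 5702 ± 818 against 2141 ± 248 CPM (log2 fold change 1.41, SE 0.23), and its adjusted p was 0.104 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without E9.5 replicate 2. Without that batch 0 of the 22 ribosomal protein genes passed over all genes and 21 adjusted over the list alone. Ribosomal protein genes have many processed copies that the counting could split, so their levels are uncertain. Of the respiratory chain genes 19 of 27 were higher, 22 when adjusted over the list alone, which became 4 and 6 without E9.5 replicate 2 and 11 and 14 without E10 replicate 3. Of the immediate early genes, which answer growth and stress signals within minutes, 16 of 20 were lower and 1 higher, and 17 were lower adjusted over the list alone, with Cyr61 at -3.36 (SE 0.25), Jun at -2.27 and Fos at -2.59 on the log2 scale. Extracellular matrix genes were lower in 11 of 22 cases, 12 adjusted over the list alone, and in 7 without E9.5 replicate 2 or without E10 replicate 3, among them Fbn2 at -3.67 and Vcan at -3.62. Each of these lists passed camera with its preset correlation and had adjusted p = 0.388 with an estimated correlation.

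The Wnt effector Lef1 stood at 5.75 ± 5.08 CPM in erythroid-like cells and 89.7 ± 36.6 CPM in the remaining clusters (log2 fold change -4.06, SE 0.47), and 9 of 15 Wnt genes were lower, the same number adjusted over the list alone, which became 5 and 6 without E9.5 replicate 2. The Notch target Hes1 was lower at -3.01 (SE 0.29), and 7 of 13 BMP and TGF-beta genes were lower, 8 adjusted over the list alone. Both lists had adjusted p = 0.388 with an estimated correlation. Glycolysis genes went both ways, with the glucose transporter gene Slc2a1 at 1.48 beside Hk1, and the pyruvate kinase gene Pkm at -1.82 and Hk2 at -2.37. Here 2 of 19 were higher and 6 lower, 2 and 7 adjusted over the list alone. In all, 22 of 30 lists passed camera with its preset correlation and 0 with an estimated correlation, where the adjusted p ranged from 0.388 to 0.959. By fry, which asks if a list's genes move on balance one way, 0 passed and the lowest adjusted p was 0.09.

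Neural or neural crest-like cells held more transcript of Isl1, a regulator of sensory and autonomic neurons, of Tbx20, a T-box gene of motor neurons and heart, and of Cdkn1c, an imprinted inhibitor of the cell cycle. Isl1 stood at 364 ± 217 CPM (mean ± SD, n = 5 batches) against 9.73 ± 6.88 CPM in the remaining clusters, a log2 fold change of 5.06 (SE 0.37) with an adjusted p of 5.39e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cdkn1c stood at 2838 ± 994 against 324 ± 106 CPM (log2 fold change 3.10, SE 0.17), Tbx20 at 82.1 ± 78.0 against 2.76 ± 1.78 CPM (4.40, SE 0.53) and the receptor gene Notch1 at 102 ± 33.6 against 18.04 ± 10.7 CPM (2.68, SE 0.41). The Notch target Hes1 was lower, at 74.5 ± 81.6 against 429 ± 262 CPM (-2.77, SE 0.30), as was the growth factor gene Igf2, at 187 ± 135 against 1474 ± 288 CPM (-3.25, SE 0.26). For Cdkn1c the adjusted p was 1.75e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each of these genes differed the same way in 5 of 5 batches. In E9.5 replicate 1, with 3 cells of the class, Isl1 stood at only 9.05 against 1.44 CPM and Tbx20 at 3.39 against 0.48 CPM. In the class sums of the other batches Isl1 stood at 331.5 to 537.7 CPM. Cdkn1c stood at 1292 against 214 CPM in E9.5 replicate 1.

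**Figure D4:**
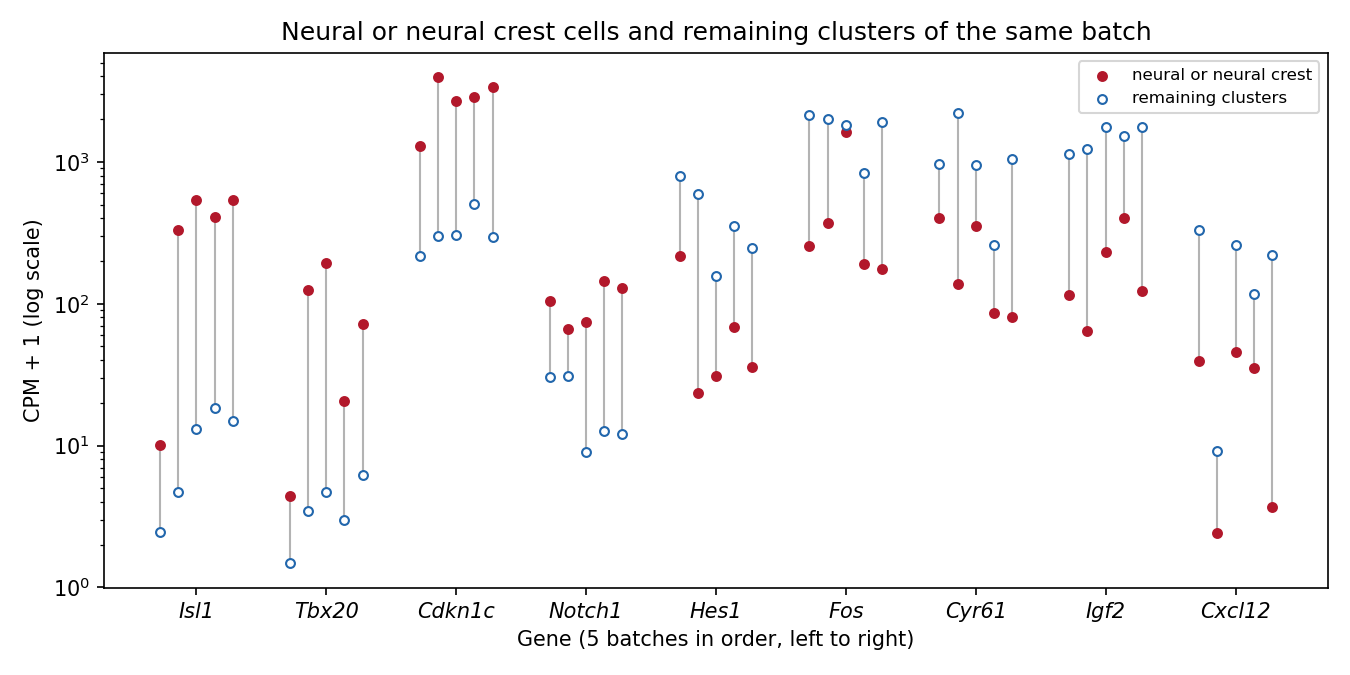
CPM plus 1, on a log axis, of Isl1, Tbx20, Cdkn1c, Notch1, Hes1, Fos, Cyr61, Igf2 and Cxcl12 in neural or neural crest-like cells and in the remaining clusters of each of the 5 batches, 1 point per sum. Isl1 averages 364 CPM against 9.73 CPM, and Igf2 averages 187 CPM against 1474 CPM.

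This comparison again read the list genes alone, and a minimum of 3 cells per batch, set after the cell numbers were seen, kept all 5 batches. The neural or neural crest-like cells were in cluster 4 in every batch. Of 445 list genes 104 passed an adjusted p of 0.05, 23 higher and 81 lower, against 194 at an unadjusted p under 0.05 and 135 by DESeq2. Without E10 replicate 3 the count was 68, of which 66 were shared. When clusters were named by mean in place of median marker levels, which added cluster 2 to the class, the count was 57, of which 54 were shared.

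Immediate early genes were lower in neural or neural crest-like cells in 14 of 20 cases, 9 without E9.5 replicate 1, and in 17 adjusted over the list alone, with Cyr61 at -2.38 (SE 0.34) and the flow-responsive gene Klf2 at -2.27 (SE 0.38) on the log2 scale. The list had an adjusted p of 1.68e-12 by camera with its preset correlation, and adjusted p = 0.154 with an estimated correlation. S-phase genes were lower in 7 of 39 cases, 18 adjusted over the list alone (adjusted p = 0.217 with an estimated correlation). These became 3 and 7 without E10 replicate 1, 11 and 22 without E10 replicate 2, and 1 and 6 without E10 replicate 3. Among them the chromatin remodeller gene Hells stood at 115 ± 51.2 against 295 ± 66.8 CPM (-1.43, SE 0.22), a difference of -0.25, no longer past the threshold, when clusters were named by mean levels. Genes that support blood cells were lower in 6 of 12 cases, 8 adjusted over the list alone, with Igf1 at -4.25 (SE 0.49) and Mdk at -1.12 (SE 0.16). Wnt genes were lower in 8 of 15 cases, 11 adjusted over the list alone, and in 5 without E9.5 replicate 2 or without E10 replicate 3, with the Wnt potentiator Rspo3 at 0.459 ± 0.516 against 28.7 ± 20.7 CPM.

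Of 11 regulators of heart development 5 were higher and 1 lower, 6 and 3 adjusted over the list alone, and the list had an adjusted p of 0.000268 by camera, in the higher direction, and adjusted p = 0.154 with an estimated correlation. Its members Isl1, Tbx20 and Hand2 also act in autonomic or motor neurons. Extracellular matrix genes went both ways, with the fibrillar collagen gene Col5a2 at 1.79 (SE 0.34) and Vcan at -2.04 (SE 0.28), 2 of 22 higher and 6 lower, 2 and 9 adjusted over the list alone, with 1 higher over all genes without E9.5 replicate 1 or without E10 replicate 1. Respiratory chain genes and ribosomal protein genes gave 0 calls each over all genes and 0 adjusted over the list alone. In all, 13 of 30 lists passed camera with its preset correlation, 0 with an estimated correlation, where the adjusted p ranged from 0.154 to 0.944, and 14 by fry.

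The stage comparison asked which genes differed between E10 and E9.5. In all kept cells the respiratory chain gene Cox6c stood at 1370 ± 288 CPM (mean ± SD, n = 2) at E9.5 and 1005 ± 173 CPM (n = 3) at E10, and the immediate early gene Ier2 at 939 ± 319 and 428 ± 102 CPM. Neither passed, at log2 fold changes of -0.45 and -1.13 (SE 0.31 for Ier2) and adjusted p-values of 0.648 and 0.615 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By that test 0 of 14104 genes passed, with 1123 at an unadjusted p under 0.05 and 90 by DESeq2, 50 higher and 40 lower at E10. As lists, the 27 respiratory chain genes (median log2 fold change -0.39), the 20 immediate early genes (-0.89) and the 22 ribosomal protein genes (-0.33) lay lower at E10 than other genes by camera with its preset correlation, at adjusted p-values of 2.32e-09, 5.19e-09 and 7.35e-06. For each the result was adjusted p = 0.981 with an estimated correlation and 0.984 by fry, and in each 0 genes passed, also adjusted over the list alone. Without E9.5 replicate 2 the ribosomal protein genes had an adjusted p of 0.509 by camera. The 3 lists became 13 without E9.5 replicate 1, 11 without E9.5 replicate 2 and 7 without E10 replicate 1. Leaving out an E9.5 batch leaves 1 sample, which is assumed to vary like the others.

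Within the remaining clusters Cox6c stood at 1360 ± 189 CPM at E9.5 and 894 ± 174 CPM at E10, and the immediate early gene Cyr61 at 1636 ± 915 and 745 ± 422 CPM. The posterior patterning gene Hoxc10 stood at 1.24 ± 1.75 and 102 ± 96.9 CPM, and Igf2bp1, an RNA-binding gene of early development, at 223 ± 72.2 and 363 ± 18.8 CPM. Hoxc10 did not separate the stages, at 2.47 and 0 CPM in the E9.5 replicates and 2.23, 195.7 and 108.5 CPM in the E10 replicates. It is a leading gene of cluster 7, which lay mainly in E10 replicate 2. Hoxc9, the other gene named from that list, went the other way, at 81.6 ± 111.4 and 60.8 ± 39.9 CPM. No gene passed, with 0 of 12558 by edgeR's quasi-likelihood test, 1570 at an unadjusted p under 0.05 and 284 by DESeq2, 136 higher and 148 lower. The count was 10 without E9.5 replicate 1 and 57 without E9.5 replicate 2. The clusters behind these sums differed, being mainly cluster 1 in E9.5 replicate 1, cluster 0 in E9.5 replicate 2, clusters 9, 2 and 3 in E10 replicate 1, cluster 7 in E10 replicate 2 and clusters 2, 1 and 0 in E10 replicate 3.

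In that group, immediate early genes (median log2 fold change -1.11), respiratory chain genes (-0.50) and ribosomal protein genes (-0.34) lay lower at E10 by camera, with adjusted p-values of 5.67e-11, 5.78e-10 and 8.94e-07, and adjusted p = 0.739 with an estimated correlation for each. Of the 20 immediate early genes 0 passed over all genes and 8 were lower adjusted over the list alone, while without E9.5 replicate 2 it was 3 over all genes. The respiratory chain, ribosomal protein, posterior Hox and early gene lists had 0 in both counts. Posterior Hox genes lay higher at an adjusted p of 0.0219 by camera, and adjusted p = 0.872 with an estimated correlation. For the posterior Hox genes it was 0.093 without E10 replicate 2 and 0.0829 without E10 replicate 3. The list of pluripotency and early genes, to which Igf2bp1 belongs, lay higher at 0.0177, and adjusted p = 0.739 with an estimated correlation. These 5 lists became 9 without E9.5 replicate 1, 8 without E9.5 replicate 2 and 8 without E10 replicate 1, and 0 passed by fry.

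In neural or neural crest-like cells the S-phase gene Nasp, a histone chaperone, stood at 747 ± 185 CPM at E9.5 and 532 ± 234 CPM at E10, the respiratory chain gene Cox4i1 at 1596 ± 246 and 858 ± 110 CPM, and the ribosomal gene Rplp0 at 4436 ± 558 and 3135 ± 589 CPM. None passed, and for Cox4i1 the log2 fold change of -0.90 had an adjusted p of 0.86 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By that test 0 of 10174 genes passed, with 584 at an unadjusted p under 0.05 and 34 by DESeq2, 29 higher and 5 lower at E10, and 15 without E9.5 replicate 2. Ribosomal protein, G2 and M phase, respiratory chain and S-phase genes lay lower at E10 by camera, with adjusted p-values of 2.47e-12, 9.5e-11, 9.21e-10 and 2.12e-09, and adjusted p = 0.764 with an estimated correlation for each. The G2 and M phase genes had a median log2 fold change of -0.09, and their UMIs per 10000 averaged 87.7 at E9.5 and 84.6 at E10 (exact permutation p = 1.0), with 42.7, 168 and 43.5 in the E10 replicates, the middle value from 4 cells. Without E9.5 replicate 2 the G2 and M phase genes had an adjusted p of 0.0529. In these lists 0 genes passed, also adjusted over the list alone, and 0 lists passed by fry.

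Whether the stage changed the classes differently was tested as an interaction. For Hand2, a regulator of autonomic neurons and of limb and heart mesenchyme, the stage difference in neural or neural crest-like cells exceeded that in the remaining clusters by 4.02 on the log2 scale (SE 0.58), with an adjusted p of 0.0185 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Hand2 stood at 1.13 and 279 CPM in the neural or neural crest-like cells of the E9.5 replicates and 743, 608 and 431 CPM in those of the E10 replicates, against 3.52 and 124 CPM, then 20.7, 45.1 and 12.5 CPM in the remaining clusters. For Pax3 the difference was -7.70 (SE 1.27), with an adjusted p of 0.0498 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It rests on values near 0, since Pax3 stood at 0 and 0.41 CPM in the remaining clusters at E9.5, and Pax3 is a fixed marker, open to use in clustering and among the leading genes of cluster 3, which lies mainly in E10 replicate 1. Its value is therefore given as a description of the groups.

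These 2 genes were the calls among 12928 tested, with 509 at an unadjusted p under 0.05 and 17 by DESeq2. The 509 are a smaller share of the genes than the 0.05 given by chance, as are those of the erythroid-like interaction below. Without E10 replicate 1 the adjusted p was 0.229 for Hand2 and 0.229 for Pax3, and for Pax3 it was 0.0804 without E10 replicate 3 and 0.32 with clusters named by mean levels, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count of genes was 7 without E9.5 replicate 1, 47 without E9.5 replicate 2, 0 without E10 replicate 1, 34 without E10 replicate 2 and 1 without E10 replicate 3. With clusters named by mean levels it was 2, of which Hand2 alone was shared. For erythroid-like cells the interaction gave 0 of 13214 genes by edgeR's quasi-likelihood test, 428 at an unadjusted p under 0.05 and 0 by DESeq2, with 1 residual degree of freedom. No list passed for them, and the lowest adjusted p was 0.155 by camera.

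In the neural or neural crest-like interaction 5 lists passed camera with its preset correlation. S-phase genes had an adjusted p of 4.83e-08 and G2 and M phase genes 2e-07, both lower, and immediate early genes 7.72e-05, higher, each with adjusted p = 0.644 with an estimated correlation. Ribosomal protein genes at 0.0185 and pluripotency and early genes at 0.0176 were lower, also with adjusted p = 0.644 with an estimated correlation. No member passed over all genes, and 1 S-phase gene and 2 pluripotency and early genes were lower adjusted over the list alone. The 5 lists became 2 without E9.5 replicate 2 and 2 without E10 replicate 3, and 0 passed by fry. The G2 and M phase genes had adjusted p-values of 0.0828 and 0.133 in those cases, and immediate early genes 0.0537 without E9.5 replicate 2 and 0.248 without E10 replicate 1. Ribosomal protein genes had 0.503 without E9.5 replicate 1 and 0.905 without E10 replicate 3, and pluripotency and early genes 0.151, 0.084 and 0.13 without E9.5 replicate 1, E9.5 replicate 2 and E10 replicate 3.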

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

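The comparison of wells between batches, the minimum of 3 cells behind the Hand2 and Pax3 tests, and the tests of an explanation for the likeness of wells were chosen only after the result was seen.

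Hand2 and Pax3 differed between cell groups in their stage difference, by the interaction of class and stage. The stage difference in neural or neural crest-like cells minus that in the remaining clusters was 4.02 on the log2 scale for Hand2 and -7.70 for Pax3. For Hand2 the mean log2 ratio of neural or neural crest-like cells to the remaining clusters was 0.04 at E9.5 and 4.61 at E10, and it rests on 2 E9.5 batches that stood at 1.13 and 279 CPM. For Pax3 the ratio was 3.01 and -1.78, with CPM of 4.52 and 15.5 in the neural or neural crest-like cells and 0 and 0.41 in the remaining clusters of the E9.5 batches. Pax3 is also a fixed marker that was open to use in clustering. The remaining clusters differ in make-up between batches. The neural or neural crest-like class may do so as well. In its E9.5 sums, of 3 and 7 cells, Isl1 stood at 9.05 and 331.5 CPM and Tbx20 at 3.39 and 123 CPM. No explanation was tested for either gene.

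Wells of E10 replicate 2 resembled the wells of the same number in E10 replicate 3. The 23 wells left out as copies comprise 20 in E10 replicate 2, 2 in E9.5 replicate 1 and 1 in E9.5 replicate 2, outside the comparisons of the report. In E10 replicate 2 the best match had the same well number in 20 of the 20 wells compared, where chance gives 0.312, which argues against a likeness of cell types alone. The values are consistent with transfer of molecules between libraries that share well barcodes, at a median of 2.17% of the UMIs of the source well. Whether the transfer took place before or during sequencing stays open. Only wells that passed the limits on genes and UMIs were compared, so wells 41 to 72 of E10 replicate 3 were not. Among these, wells 42 and 64 held 4762 and 623 UMIs, against 547445 and 81140 in the same wells of E10 replicate 2. Transfer in that direction was not examined. The compared wells also held under 10% of the UMIs of the same-numbered well, so transfer into other kept wells was not measured. The kept sums of E10 replicates 2 and 3 may therefore share molecules, as may those of the E9.5 replicates.

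Spike-in rows, which are added RNA and no genes of the mouse, held 4.33% of all UMIs over all 480 columns, left-out wells included. They were not used in the comparisons. Their share was 3.75%, 2.50%, 6.56%, 2.02% and 2.96% in E9.5 replicates 1 and 2 and E10 replicates 1, 2 and 3. A further 65 columns held at least 1 UMI but were left out, the 23 copied wells among them and the others below the limits on genes and UMIs. Both stood above the limit that a count of 0 allows. Groups of 2 and 3 batches were not tested for a single sample far from the others.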

How the results depend on the processing

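Tests that kept copied wells, named clusters by mean levels, left out the blood classes or used a minimum of 3 cells were chosen only after the data were seen. The same holds for thinned cells in the fit of the remaining clusters and for every alternative of the neural or neural crest-like fits and of the interactions.

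Counts of called genes depended on the tool and the filter in the stage comparisons. With the DESeq2 test 0 became 90 in all cells, 284 in the remaining clusters and 34 in neural or neural crest-like cells, and 2 became 17 in the interaction. Without a low count filter the counts were 281, 66 and 18 in the last 3, and the cause was not tested. A minimum of 5 cells gave 163 genes in neural or neural crest-like cells, with 3 batches left. Leaving out cells over 5% globin gave 34 in the interaction, because E10 replicate 2 then lost its neural or neural crest-like sum. Leaving out 1 batch gave 0 to 57 genes in the remaining clusters, 0 to 15 in neural or neural crest-like cells, 96 to 223 in the erythroid-like comparison, 68 to 117 in the neural or neural crest-like comparison and 0 to 47 in its interaction. Naming clusters by mean levels gave 57 genes in the neural or neural crest-like comparison, for which the class itself changed.

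Without the replicate block the neural or neural crest-like comparison called 43 genes, all 43 shared with the 104 of the blocked fit, and the erythroid-like comparison 179, of which 175 were shared with the 220. No paired analysis of the stages was possible because each batch holds 1 stage.

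Calls of gene lists depended on the correlation assumed between genes. With an estimated correlation 0 lists passed in place of 3 in all cells, 5 in the remaining clusters, 4 in neural or neural crest-like cells, 22 and 13 in the erythroid-like and neural or neural crest-like comparisons and 5 in the interaction. By fry 0 passed in each of these but the neural or neural crest-like comparison, with 14. Leaving out 1 batch gave 3 to 13 lists in all cells, 4 to 9 in the remaining clusters and 2 to 5 in the interaction.

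The sign changed for Rplp1, Hmga2, Hoxc9, Hmgb2 and Cbx5 in stage comparisons, where none was past the threshold, and for Hoxc10 in a class comparison, where it was past it. Leaving out 1 batch moved Rplp1 between -0.36 and 0.22 in all cells and between -0.17 and 0.0618 in the remaining clusters, Hmga2 between -0.33 and 1.09 and Hoxc9 between -1.39 and 4.43 in the remaining clusters, and Hmgb2 between -1.16 and 0.61 and Cbx5 between -0.54 and 0.0635 in neural or neural crest-like cells. Hmgb2 was at -1.16 without cells over 5% globin and -1.60 with a minimum of 5 cells (adjusted p = 0.00564 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Cbx5 at 0.0282 with clusters named by mean levels, and Hoxc10 at 0.0706 against -3.69 in the neural or neural crest-like comparison with clusters named by mean levels. The cause was not tested.

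Of the other values for single genes, 981 kept their direction and side of the threshold under the alternatives written before the data were seen and 80 lost the call, and under those added later 1328 and 160. DESeq2 size factors moved no count of genes by over 1.5 times. Differences in share with stage ranged over the alternatives from -5.01 to 12.9 percentage points for erythroid-like cells, -3.43 to 5.27 for haematopoietic progenitor-like cells, -5.91 to 9.11 for neural or neural crest-like cells, 0 to 10.9 for Dppa5a-led cells and -28.8 to 1.5 for the remaining clusters, and none moved by more than the spread between batches. With expression centred per batch 0 cells were named haematopoietic progenitor-like and the remaining clusters held 196 cells, so that class did not hold under every alternative. Not run were equal weights for each class, which needs cells of each class in every batch, a minimum of 20 cells for the neural or neural crest-like class, and removal of globin-rich cells from the erythroid-like class. At this depth and with 5 batches, most 2-fold and 4-fold changes with stage were out of reach. Simulated changes of these sizes were recovered in 1.49% and 28.4% of cases in all cells. Of 8-fold changes 66.7% were recovered there and 34.8% in neural or neural crest-like cells. The absence of calls therefore does not exclude large changes.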

Other observations

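The tests of an explanation for the Dppa5a-led cells and for the haemoglobin counts were chosen only after the result was seen, while the other splits of the batches were planned.

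Imprinted genes that act on growth differed in the class comparisons. Against the remaining clusters, erythroid-like cells were lower in the mesodermal gene Mest, at 11.1 ± 7.40 against 127 ± 7.32 CPM (mean ± SD, n = 3 batches, log2 fold change -3.70), in the non-coding RNA gene Meg3 at -3.23 and in the zinc finger gene Peg3 at -3.85. The non-coding RNA gene H19 was higher at 1.64 (SE 0.23), at 4115 ± 1390 against 1359 ± 629 CPM, and its adjusted p was 0.0645 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without E9.5 replicate 2. Of 18 imprinted genes 11 were lower and 1 higher, 15 and 1 adjusted over the list alone, with adjusted p = 0.388 with an estimated correlation. In neural or neural crest-like cells 3 were higher and 5 lower, 4 and 7 adjusted over the list alone, with Mest at -2.21 and H19 at -1.04.

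Posterior Hox genes, which pattern the trunk, were lower in erythroid-like cells in 11 of 17 cases, 16 adjusted over the list alone, and in 5 without E9.5 replicate 2 and 7 without E10 replicate 3 over all genes. Among them Hoxc9 stood at 4.32 ± 3.53 against 80.3 ± 32.8 CPM (log2 fold change -4.29, SE 0.51) with an adjusted p of 5.38e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In neural or neural crest-like cells 2 of 17 were lower, 4 adjusted over the list alone, and 0 in both without E10 replicate 3. Over all genes 1 was lower without E10 replicate 1, and adjusted over the list alone 8 were lower without E9.5 replicate 1 and 2 without E10 replicate 2. Of 12 Notch pathway genes 3 were higher and 1 lower in that class, 3 and 1 adjusted over the list alone, the higher ones including the target Heyl at 4.89 (SE 0.71) and the receptor gene Notch1 at 2.68, and the list had an adjusted p of 0.476 by camera.

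Dppa5a-led cells were found in E10 replicate 1 alone. Their share was 21.9% there and 0 of 136 cells in E10 replicates 2 and 3 together. With an upper limit of 2.68%, the latter lay outside the exact interval of E10 replicate 1, 14.1% to 31.5%, where a property of the E10 stage was predicted to place it. Such a property stays open, since these intervals hold counting error only. The share of erythroid-like cells, which the sort can set, ranged over 30.9 percentage points among the E10 batches, more than this difference. RNA shared among the wells stays open, since the median Dppa5a level was 908 times that of the other cells of the plate, at 2940 and 3.24 CPM, but Dppa5a leads the cluster by such a ratio. Primordial germ cells stay open as well, since 2 of 8 markers, Dppa5a and Nanog, passed the rule for names, which does not exclude a cell type. A source outside the embryos could also give these cells and was not tested.

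Haemoglobin UMIs in cells outside the blood clusters were set against exchange of molecules within a plate and against RNA of whole erythroid cells. A first test without correction gave ratios of 5.52, 2.13 and 3.8 of the globin level to that of other erythroid markers in E9.5 replicate 2, E10 replicate 2 and E10 replicate 3. One globin gene held up to 44698 of the 65536 possible UMIs in a cell, so a correction for UMI collisions and a new rule were set after that result. With it the ratios were 5.05, 1.77 and 2.72, and both explanations needed them under 2 in every batch, so neither was met in E9.5 replicate 2 and E10 replicate 3. Exchange also needed a ratio under 2 for globins over neural genes, where the highest was 1.81, next to 1.21 and 1.25. To exclude either explanation took ratios of at least 2 in every batch, which 1.77 in E10 replicate 2 did not give, so exchange and erythroid RNA stay open and cannot be told apart.

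Other splits of the sums of the batches were counted for the class comparisons. For neural or neural crest-like cells the real count was 104 list genes, and among the 16 splits that part every batch 1 was as large, the real one, with 2 genes as the highest other. Among 85 splits drawn from all 126 the highest other was 13. For erythroid-like cells the real count was 220, 1 of 4 such splits was as large, and the highest other was 0. The splits that part every batch are too few for a share under 5%, at 6.25% and 25% for the smallest. Each other split puts sums of both classes in the same group, so the class differences enter its residual spread. Low counts in the other splits were therefore to be expected and do not show how many genes an unrelated grouping would call.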
